A study of Rattus norvegicus with 6 samples.

How the data were processed

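The series holds 6 single-cell RNA libraries from the brain of Sprague Dawley rats, 3 labelled sham and 3 labelled pontine infarction. Groups were taken from the group field of the sample labels and replicate numbers from the sample titles. Each sample came with a sparse matrix of raw UMI counts per gene and cell barcode, with its gene and barcode lists. The deposited counts were made with Cell Ranger 3.1.0 from reads converted with CASAVA 1.8, per the submitters' processing notes, which also name Seurat 2.3.4. The genome build and annotation are not given in the sources used here. From the values, the matrices were already restricted to called cells, since the lowest barcode held 500 UMIs. All analysis started from these counts, and gene names were those the files pair with Ensembl identifiers.

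The files list 25399 genes, of which 19105 had at least 1 UMI in the kept cells. Of 121 symbols with several identifiers, each was given to the identifier with the most UMIs, and the others were kept apart under their own identifier. Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% of UMIs from the 13 mitochondrial genes, which left 38685 of 44011 barcodes. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, and cells with a score above 0.25 were removed, 1.82% to 2.72% per library. Its automatic threshold had not worked in 2 infarction libraries, where it marked 0.0167% and 0% of cells, so it was used only as an alternative, and the score of 0.25 was set after seeing this. This left 37843 cells, 5904, 6327 and 6548 in sham 1 to 3 and 5868, 7255 and 5941 in infarction 1 to 3.

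Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes were reduced to 30 principal components. A graph of 15 neighbours was clustered with the Leiden method at resolution 1.0, with no correction between libraries, which gave 30 clusters. Marker genes of 20 cell classes were fixed before the data were examined, and the scoring rule was set afterwards. A marker counted for a cluster when at least 25% of its cells held a UMI and its CPM, with 5 added, was at least 1 log2 unit above that of all other cells summed. A cluster took the name of the class with the most such markers, at least 3. It stayed unnamed where its 10 genes with the highest fold, detected in at least 10% of cells, held more markers of another class. It also stayed unnamed where its median UMI count was under its own samples' median divided by 3 with no marker of the class among those 10. This named 22 clusters and left 8 unnamed, which held 491 sham and 5659 infarction cells, 2.64% and 29.3% on average. Names are given as X-like because they rest on these markers alone.

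Shares of cells were compared with an exact two-sided permutation test over the 20 assignments of the 6 libraries, whose smallest p is 0.1. The numbers of cells were also fitted with edgeR's quasi-likelihood test, with the total of kept cells as library size. For expression, counts were summed per library and class, for each class with at least 20 cells in every library, and over all cells. Sums were fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, TMM factors, filterByExpr), with group as the only term. The SE of a log2 fold change is its size divided by the square root of the F statistic, and is left out where F is close to 0. Genes were called at an adjusted p (Benjamini-Hochberg within a class) under 0.05. The difference between the 2 tested classes with the most cells was the interaction of class and group, with the library as a block. The sums ranged from 247600 UMIs, in endothelial cells of 1 library, to 62882052 over all cells.

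The rule for named genes was fixed before the data were examined. For each class it took genes called, with a mean CPM of at least 20 in the higher group and no overlap between groups, and named the 10 with the highest and the 10 with the lowest fold change. Unnamed gene models and mitochondrially encoded genes were left out. For each list called in a class it added up to 4 members with the smallest p. Genes of the class difference are among those with the smallest p. Sources of cytokine and growth factor transcripts were given for members of the fixed lists.

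A total of 34 gene lists for glial, immune, vascular, neuronal and stress states were fixed before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 on log CPM with a prior count of 2, adjusted over all 185 list and class pairs. Of the list members, 1 is counted with its list but its own values are not reported here. Camera with an estimated correlation and fry were run beside it. Counts of members are given over all genes tested and adjusted over the list alone, a second Benjamini-Hochberg adjustment within the list.

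Free RNA carries transcripts of abundant cells into every droplet. Each gene's level in a class was therefore set beside its highest class, with 5% as a mark. As an alternative chosen after seeing the data, 10% of a library's own profile was subtracted from each class sum. This exceeds the sham level of 38 of the 40 pericyte and smooth muscle genes called lower in microglia, macrophage, oligodendrocyte and T or NK-like cells, so a call lost this way does not show free RNA. Folds against a group at 0 were computed against a floor of 3 counts over the group and are lower bounds. With 1 to 3 counts the ratio is given with its 95% counting interval. Intervals and limits cover counting error only. Shares of cells with a UMI have Wilson 95% intervals in the tables.

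Each fit was tested on simulated counts drawn from the real means and library sizes, with 200 genes raised or lowered, 100 by 2-fold and 100 by 4-fold. The fits recovered 42% and 77% in macrophages (9775 genes), 76% and 92% in microglia (10146), 6% and 57% in oligodendrocytes (7724), 31% and 91% in T or NK cells (4367), 40% and 83% in endothelial cells (5788) and 33% and 64% over all cells (14425). The interaction recovered 71.5% of 200 genes at 4-fold (9777). The list step recovered the 1 list raised 2-fold and the abundance step the 1 class raised 4-fold.

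Alternatives fixed beforehand were DESeq2 1.42.0 and its size factors, no filter on low counts, each library left out in turn, the replicate number as a block, sums thinned to the shallowest library and genes under 5% of their highest class left out. At most 10% mitochondrial UMIs, doublets kept and clustering at resolution 0.5 were also fixed beforehand. A range over a gene's alternatives leaves out settings where the gene had too few counts to be tested. Automatic doublet thresholds, subtraction of free RNA, perivascular macrophages alone, macrophages drawn at random to their number and depth, microglia without the cycling cluster, oligodendrocyte precursors alone under automatic doublet thresholds, and shares without smooth muscle, pericyte and choroid plexus cells were added after seeing the data. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Classes with under 20 cells in some library, such as neutrophils in sham, were compared by share only.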

Results

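Gene expression was measured in single cells from the brain of Sprague Dawley rats, labelled as postnatal day 21 (a label that may mean another kind of day, and does not say whether it is the age at the operation or at sampling), in 6 droplet libraries of 3′ ends. The labels put 3 libraries in a sham group and 3 in a pontine infarction group, and the series title names the pons after stroke. The comparison asked how the mix of cells and the expression within each cell class differed after an infarct of the pons, the part of the brainstem that carries the corticospinal tracts. No time after the infarction is given in the sources used here. The labels number the replicates 1 to 3 in each group without saying how the animals were shared out, so p-values measure the spread between these samples, which may be technical.

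The deposited matrices held 44011 cell barcodes, between 6399 and 8649 per library. Total UMI counts were 56416475, 69924334 and 59554144 in sham 1, 2 and 3, and 63847395, 66748442 and 65921813 in infarction 1, 2 and 3. After filters on depth, mitochondrial share and doublets, 37843 cells were kept. The median UMI count per kept cell was 7334, 7792.5 and 7415 in sham and 9225, 7841 and 9630 in infarction, with 1898 to 2244 genes. Mitochondrial genes took a median of 9.98%, 10.2% and 9.67% of UMIs in sham and 5.61%, 7.81% and 7.21% in infarction. Within microglia-like cells the medians went the other way, 4.84% to 5.11% in sham and 7.38% to 7.47% in infarction. So they did in T or NK (4.75% to 5.76%, 6.84% to 9.30%) and endothelial-like cells (6.75% to 8.37%, 11.8% to 14.5%). Oligodendrocyte, fibroblast and pericyte-like cells did likewise. Within a group, gene totals differed between libraries beyond sampling noise (chi-square 47.9 to 384 per degree of freedom), which does not tell animals from repeated captures, and by their replicate numbers all 6 were treated as separate samples. Below, log2 fold changes are infarction over sham with their SE, levels in CPM (UMI counts scaled to the TMM-adjusted library total) are means ± SD, and n = 3 libraries per group throughout.

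Kept sham cells were mostly vessel wall, and kept infarction cells mostly immune cells. Smooth muscle-like cells, placed by contractile markers such as Tagln, Acta2 and Myh11, made up 36.3% ± 5.76 of kept sham cells (SD, n = 3), and 0 cells were found in infarction. A count of 0 allows a share of up to 0.0414% to 0.0511% per library, for counting error alone. Pericyte-like cells, which wrap capillaries, fell from 24.4% ± 4.89 to 0.0783% ± 0.00884. At most 10% mitochondrial UMIs gave differences of -12.0 (smooth muscle) and -26.7 percentage points (pericytes). Macrophage-like cells rose from 2.07% ± 0.270 to 28.5% ± 7.08, and neutrophil-like cells from 0.366% ± 0.286 to 23.6% ± 9.95. Without smooth muscle, pericyte and choroid plexus cells, a denominator chosen after seeing the data, these rises were smaller, from 6.30% ± 2.69 to 28.5% and from 1.07% ± 0.785 to 23.6%, and unnamed cells went from 8.37% ± 5.02 to 29.4%. Astrocyte-like cells went from 4.36% ± 2.90 to 0.404% ± 0.430, fibroblast-like cells from 2.28% ± 1.0 to 0.255% ± 0.0961, choroid plexus-like cells from 3.15% ± 2.91 to 0.0204% ± 0.0179 and neuron-like cells from 1.07% ± 1.10 to 0.0158% ± 0.0169.

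For these 8 classes, and for the cells left unnamed, every infarction library lay on 1 side of every sham library. The exact two-sided permutation test gave p = 0.1 for each, the smallest value that 3 against 3 allows, or 0.156 adjusted over the 14 classes. An edgeR model of cell numbers called all 9. On the log2 scale it gave -8.25 ± 0.527 for pericytes (adjusted p = 8.60e-06), -7.11 ± 1.41 for choroid plexus (adjusted p = 0.00254), -5.92 ± 1.14 for neurons (adjusted p = 0.00251) and -3.14 ± 0.551 for fibroblasts (adjusted p = 0.00155). Smooth muscle had an adjusted p of 4.72e-05, with no fold because 1 group stood at 0. The increases were 3.78 ± 0.434 for macrophages (adjusted p = 0.000177), 6.0 ± 0.764 for neutrophils (adjusted p = 0.000343) and 3.47 ± 0.496 for unnamed cells (adjusted p = 0.000457). With automatic doublet thresholds, chosen after seeing the data, the macrophage value was 1.10 with an adjusted p of 0.166, because the naming rule there left the cluster led by Apoc1, Fabp4 and Spp1 unnamed, with 0 sham cells and 848, 1507 and 1568 infarction cells. The astrocyte change of -3.43 ± 1.05 (adjusted p = 0.0209) was not called without sham 1 (-3.60, adjusted p = 0.0680) or infarction 2 (-3.26, adjusted p = 0.0765).

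**Figure D1:**
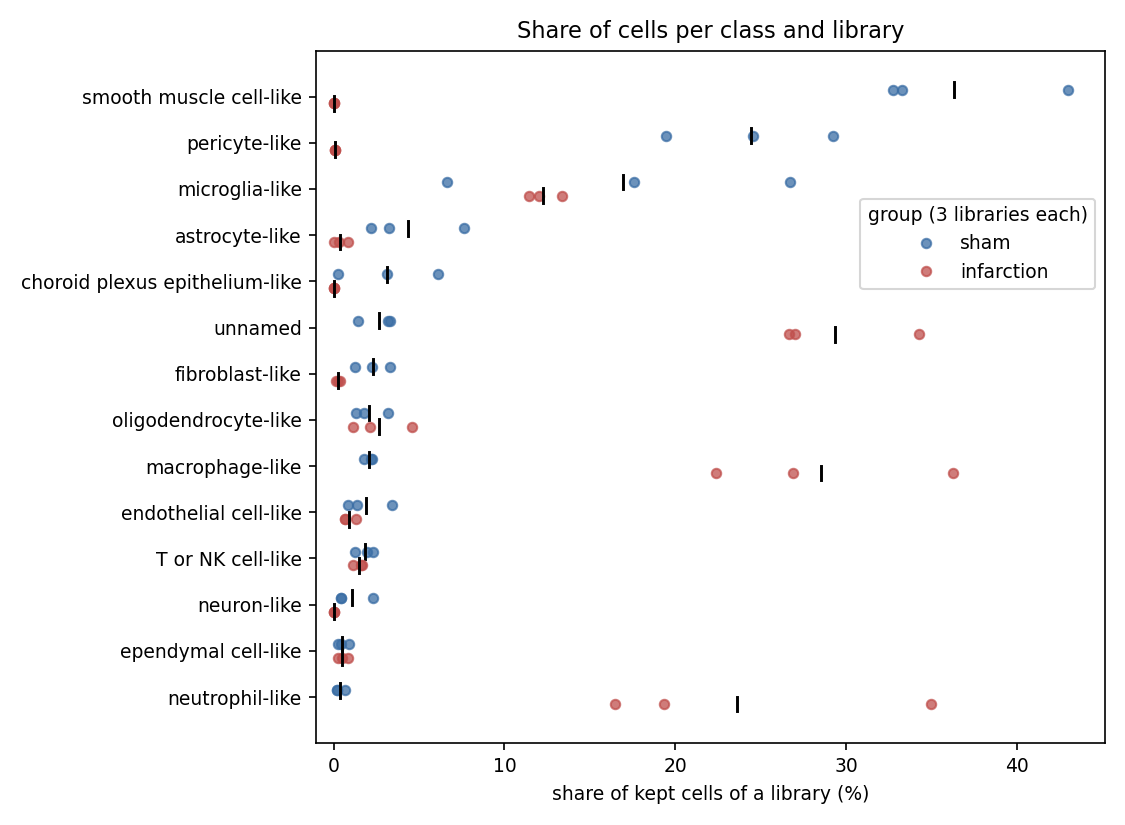
Share of kept cells (%, horizontal axis) in each cell class, with 1 dot per library and a bar at the mean of 3 libraries, for sham and pontine infarction. Smooth muscle-like cells averaged 36.3% in sham and 0% in infarction, and macrophage-like cells 2.07% and 28.5%.

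For the remaining classes the shares overlapped between groups. Microglia-like cells held 17.0% ± 10.0 of sham and 12.3% ± 0.999 of infarction cells (exact permutation p = 0.6, edgeR adjusted p = 0.532). T or NK-like cells held 1.84% ± 0.542 and 1.47% ± 0.285 (exact permutation p = 0.4, adjusted p = 0.549), oligodendrocyte-like cells 2.09% ± 0.964 and 2.64% ± 1.78 (exact permutation p = 0.7, adjusted p = 0.655) and ependymal-like cells 0.522% ± 0.337 and 0.524% ± 0.281 (exact permutation p = 1, adjusted p = 0.992). Endothelial-like cells held 1.88% ± 1.35 and 0.883% ± 0.358 (exact permutation p = 0.2, adjusted p = 0.171), and were called lower without sham 3 (-1.44, adjusted p = 0.0355). Without smooth muscle, pericyte and choroid plexus cells, microglia, again without that unnamed cluster, fell from 43.9% ± 15.2 to 12.3% ± 1.0 (log2 -1.84, adjusted p = 0.0154). Endothelial cells then changed by -2.66 (adjusted p = 0.00148) and T or NK cells by -1.94 (adjusted p = 0.0138). With at most 10% mitochondrial UMIs, ependymal cells changed by -2.11 (adjusted p = 0.0115), endothelial cells by -3.69 (adjusted p = 0.000616) and T or NK cells by -1.49 (adjusted p = 0.0358).

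In microglia, macrophage and pericyte-like cells, different clusters held most cells in each group. Of sham pericyte-like cells 68.1% were in a cluster led by Ndufa4l2, and 14 of the 15 infarction ones in a cluster led by Atp13a5. Of the 3 smooth muscle clusters, 1 was led by Rasd1, with the immediate early genes Fos and Nr4a1, which tissue dissociation also induces, 1 by Rergl and 1 by Eln, Actg2 and Cnn1. Of sham microglia-like cells, 72.6% were in a cluster led by Tmem119 and P2ry12, and 23.6% in a shallow cluster with a median of 991 UMIs. Of infarction microglia-like cells, 66.0% were in a cluster led by Ccl4, Gpr84 and C1qb, and 25.6% in a cycling cluster led by Mki67 and Top2a. Sham macrophage-like cells lay almost wholly (99.7%) in a cluster led by Cxcl13, Lyve1 and Mrc1, genes of perivascular macrophages. In infarction that cluster held 2.79% of the class, while 77.3% lay in a cluster led by Apoc1, Spp1, Fabp4, Fabp5 and Gpnmb and 19.9% in one led by the interferon-induced genes Mx1, Cxcl10 and Ifit2. Clusters without a name rose from 2.64% ± 1.05 to 29.3% ± 4.30 of cells. They included 1 led by Fcnb, Vcan and Ccr1 (0.154% to 12.9%) and 1 of cycling cells with few UMIs, whose best-scoring class was microglia (0.284% to 6.18%). Others were 1 led by Ccl17, Ccl22 and RT1-Bb (0.234% to 6.05%) and 1 led by Clec9a and Klrc2 (0.0971% to 2.26%).

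Summed over all cells, the libraries carried this change of cell mix. Spp1 (ENSRNOG00000043451), which encodes the secreted phosphoprotein osteopontin, rose from 25.4 ± 7.90 to 17202 ± 4151 CPM (log2 fold change 9.40 ± 0.41, adjusted p = 1.61e-05). Ccl2, a chemokine that draws monocytes, rose from 11.6 ± 5.42 to 5015 ± 2203 CPM (log2 fold change 8.76 ± 0.63, adjusted p = 7.47e-05). The phagocyte glycoprotein gene Gpnmb rose by 9.55 ± 0.33, adjusted p = 1.14e-05, and Arg1 (ENSRNOG00000013304), encoding arginase, by 9.81 ± 0.46, adjusted p = 1.97e-05. Tagln (ENSRNOG00000017628), encoding the smooth muscle protein transgelin, fell from 15100.2 ± 2435 to 4.35 ± 3.76 CPM (log2 fold change -11.76 ± 0.87, adjusted p = 8.04e-05). Slco1a2, an organic anion transporter gene highest in choroid plexus, had 0 UMIs in infarction and was at least 2266-fold lower, taking a floor of 3 counts over the group.

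Of 14614 genes tested, 4860 rose and 5576 fell, at 50978586 to 62882052 UMIs per library. The groups did not overlap in 11368 (77.8%), where chance gives 10%. Pericyte and smooth muscle genes fell (15 of 15 fell, 15 adjusted over the list alone, camera adjusted p = 4.95e-07, adjusted p = 0.502 with an estimated correlation). Proliferation genes such as Mcm5 (3.65 ± 0.20) rose (24 of 24 rose, 24 adjusted over the list alone, camera adjusted p = 2.23e-08, adjusted p = 0.502 with an estimated correlation). Cytokines and chemokines rose (20 of 26 rose and 1 fell, 20 up and 1 down adjusted over the list alone, camera adjusted p = 6.25e-05). NF-kappa-B feedback genes (15 of 16 rose and 1 fell, 15 up and 1 down adjusted over the list alone, camera adjusted p = 8.21e-05) and the type I interferon response, with Ifit3 at 4.94 ± 0.57 (19 of 26 rose, 19 adjusted over the list alone, camera adjusted p = 0.000290), rose as lists. So did MHC class II presentation, with Cd74 at 2.90 ± 0.15 (9 of 10 rose, 9 adjusted over the list alone, camera adjusted p = 0.00122). MHC class I presentation genes rose (12 of 14 rose, 12 adjusted over the list alone, camera adjusted p = 0.000519). The adjusted p of the 20 called lists was 0.441 to 0.632 with an estimated correlation.

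Phagocyte and metabolic lists also rose over all cells. These were lysosome genes (16 of 21 rose and 1 fell, 16 up and 1 down adjusted over the list alone, camera adjusted p = 8.54e-05) and disease-associated microglia genes (17 of 21 rose and 3 fell, 17 up and 3 down adjusted over the list alone, camera adjusted p = 0.000212). Lipid efflux and droplet genes rose (12 of 17 rose and 2 fell, 12 up and 2 down adjusted over the list alone, camera adjusted p = 0.000325). Hypoxia and glycolysis genes (19 of 23 rose and 2 fell, 19 up and 2 down adjusted over the list alone, camera adjusted p = 5.07e-05) rose. The unfolded protein response (15 of 16 rose and 1 fell, 15 up and 1 down adjusted over the list alone, camera adjusted p = 0.000215) did too. Iron and haem genes, with the ferritin gene Fth1 at 3.37 ± 0.19 and the haem oxygenase gene Hmox1 at 4.54 ± 0.45, rose (10 of 14 rose, 10 adjusted over the list alone, camera adjusted p = 0.00772). Astrocyte transport genes such as the sodium pump subunit gene Atp1b2 (-5.90 ± 0.49) fell (1 of 18 rose and 17 fell, 1 up and 17 down adjusted over the list alone, camera adjusted p = 0.00396). Cilia genes fell (13 of 15 fell, 13 adjusted over the list alone, camera adjusted p = 0.0122). Extracellular matrix genes fell as a list (5 of 26 rose and 19 fell, 5 up and 19 down adjusted over the list alone, camera adjusted p = 0.0122). The basement membrane collagen gene Col4a1 stood at -5.60 ± 0.24, and Vcan, which went the other way, at 5.67 ± 0.21. Oligodendrocyte precursor genes fell (1 of 14 rose and 11 fell, 1 up and 11 down adjusted over the list alone, camera adjusted p = 0.0223).

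The weakest calls over all cells rested on 1 or 2 libraries. Antioxidant genes (10 of 16 rose and 1 fell, 10 up and 1 down adjusted over the list alone, camera adjusted p = 0.0339), which rose, were not called without sham 3 (adjusted p = 0.0520). Genes of p53 and apoptosis, which rose (9 of 17 rose and 1 fell, 8 up and 1 down adjusted over the list alone, camera adjusted p = 0.0354), were not called without sham 3 (adjusted p = 0.0607) or infarction 1 (adjusted p = 0.0549). Cholesterol biosynthesis genes, which fell (3 of 24 rose and 16 fell, 3 up and 16 down adjusted over the list alone, camera adjusted p = 0.0371), were not called without sham 3 (adjusted p = 0.0570). The adjusted p of the 20 lists ran from 5.32e-09 to 0.632 over their alternatives, the highest values coming with an estimated correlation.

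In microglia-like cells, the disease-associated microglia list rose and the homeostatic list fell. Spp1 rose from 19.5 ± 7.93 to 9162 ± 2508 CPM (log2 fold change 8.94 ± 0.53, adjusted p = 0.000111). Lgals3 (ENSRNOG00000010645), encoding a galectin of phagocytes, rose from 7.72 ± 1.56 to 1001 ± 96.0 CPM (log2 fold change 7.09 ± 0.13, adjusted p = 2.72e-10), and Gpnmb from 8.40 ± 4.10 to 727 ± 49.8 CPM (log2 fold change 6.25 ± 0.26, adjusted p = 3.28e-06). Spp1, Lgals3 and Gpnmb are among 20 abundant macrophage genes, all higher here, so a part from macrophages is left open. The scavenger receptor gene Msr1 rose by 6.17 ± 0.19, adjusted p = 6.05e-09. Cx3cr1 (ENSRNOG00000018509), the fractalkine receptor gene, fell from 568 ± 19.5 to 141 ± 9.66 CPM (log2 fold change -2.01 ± 0.08, adjusted p = 1.87e-08). Csf1r, encoding a receptor that microglia need to survive, fell by 1.27 ± 0.08 on the log2 scale (adjusted p = 3.11e-07). All homeostatic microglia genes tested fell (16 of 16 fell, 16 adjusted over the list alone, camera adjusted p = 9.09e-07, adjusted p = 0.502 with an estimated correlation). Without the cycling cluster all 16 still fell, with a median of -1.89. The disease-associated microglia list rose (14 of 21 rose and 1 fell, 14 up and 1 down adjusted over the list alone, camera adjusted p = 0.000380, adjusted p = 0.466 with an estimated correlation). Cx3cr1 and C3 also lead the cluster that held most sham microglia. Members of the disease-associated list moved apart: Itgax, an integrin subunit gene, changed by 4.89 ± 0.25 and the lipid receptor gene Trem2 by -1.70 ± 0.10.

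**Figure D2:**
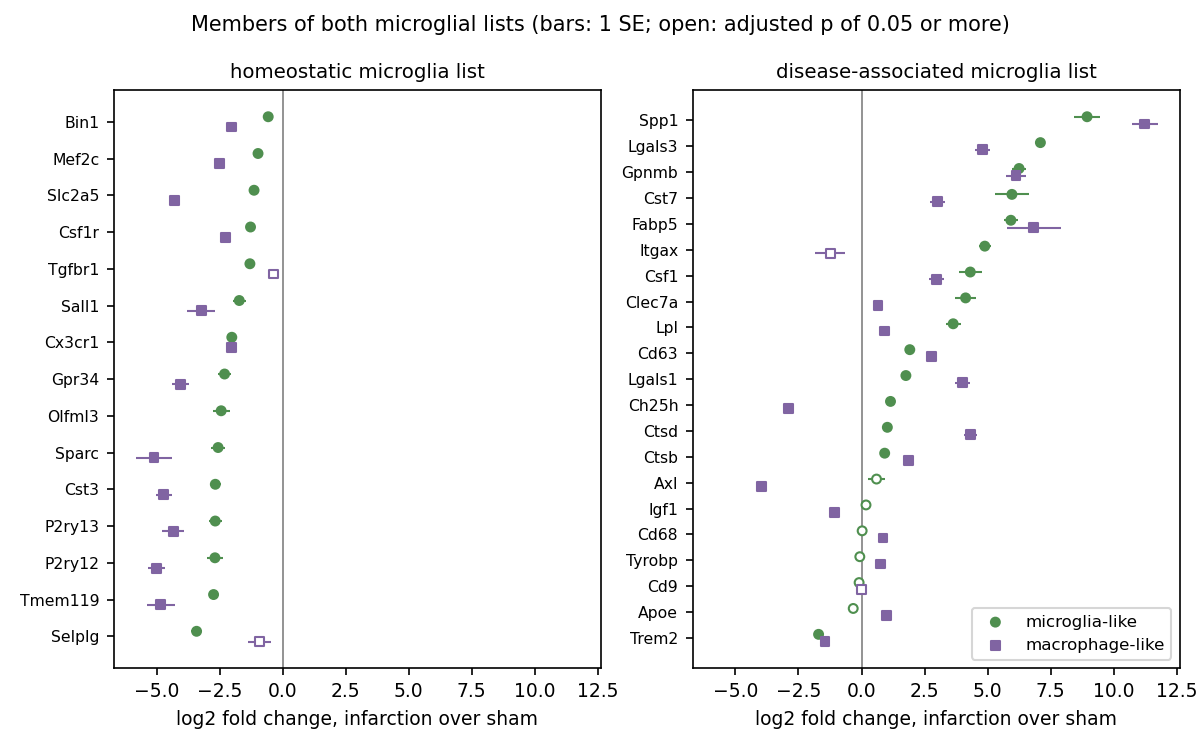
Log2 fold change, pontine infarction over sham (3 libraries per group), of members of the homeostatic and the disease-associated microglia lists (1 homeostatic member is not shown), in microglia-like and macrophage-like cells, with bars of 1 SE (none where the change is too near 0 to give one) and open marks for an adjusted p of 0.05 or more. In microglia 16 of 16 homeostatic members fell, and 14 of 21 disease-associated members rose and 1 fell.

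Cell cycle genes rose in microglia without exception in the list (24 of 24 rose, 24 adjusted over the list alone, camera adjusted p = 6.77e-11, adjusted p = 0.466 with an estimated correlation). Mcm6, part of the replicative helicase, changed by 2.90 ± 0.10, adjusted p = 8.88e-09, and Pcna, the polymerase clamp gene, by 1.92 ± 0.08, adjusted p = 2.58e-08. Genes of this kind define the cycling cluster, and outside it 24 of 24 rose, with a median of 3.39. Nuclear genes of the mitochondrial respiratory chain rose (22 of 27 rose and 1 fell, 22 up and 1 down adjusted over the list alone, camera adjusted p = 1.08e-05), Cox5a by 1.38 ± 0.06. Hypoxia and glycolysis genes rose (17 of 21 rose and 3 fell, 17 up and 3 down adjusted over the list alone, camera adjusted p = 0.000315). In that list the lactate dehydrogenase gene Ldha changed by 2.23 ± 0.07 and Pgk1 by 2.22 ± 0.08, while the hexokinase gene Hk2 went the other way, by -1.98 ± 0.08. Cholesterol biosynthesis genes fell (1 of 22 rose and 15 fell, 1 up and 15 down adjusted over the list alone, camera adjusted p = 0.00244), with their transcription factor Srebf2 at -1.48 ± 0.13. Complement genes fell (11 of 14 fell, 11 adjusted over the list alone, camera adjusted p = 0.00494). C3 fell from 933 ± 126 to 177 ± 7.09 CPM (log2 fold change -2.40 ± 0.10, adjusted p = 3.25e-08), and C1qa stood at -1.16 ± 0.11. All 13 lists called in microglia had an adjusted p of 0.441 to 0.619 with an estimated correlation.

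Cytokine and chemokine genes rose in microglia (12 of 20 rose and 2 fell, 14 up and 2 down adjusted over the list alone, camera adjusted p = 0.00432). Ccl12 changed by 4.74 ± 0.36, adjusted p = 7.64e-05, and Il6 by 1.41 ± 0.15, adjusted p = 1.68e-05. Antioxidant genes rose (9 of 16 rose and 1 fell, 9 up and 1 down adjusted over the list alone, camera adjusted p = 0.0206), with the peroxiredoxin gene Prdx1 at 2.35 ± 0.07 and the thioredoxin gene Txn1 at 2.22 ± 0.13. NF-kappa-B feedback genes rose (8 of 16 rose, 8 adjusted over the list alone, camera adjusted p = 0.0223), Ptgs2, a prostaglandin synthase gene, by 5.76 ± 0.41, but not once 10% of the library's profile was subtracted (adjusted p = 0.121), an amount that can exceed the free RNA present. Members of the reactive astrocyte list rose (10 of 20 rose and 4 fell, 10 up and 4 down adjusted over the list alone, camera adjusted p = 0.0411), and 9 of the 20 stood under 5% of their level in another class. One member, the hyaluronan receptor gene Cd44, changed by 5.53 ± 0.22. The unfolded protein response (12 of 16 rose and 1 fell, 12 up and 2 down adjusted over the list alone, camera adjusted p = 0.0494) was called higher, with Manf at 0.80 ± 0.10, but not without sham 1 (adjusted p = 0.0549), sham 2 (adjusted p = 0.0793) or infarction 2 (adjusted p = 0.0627). The adjusted p of these lists reached 0.619 with an estimated correlation, and over all alternatives the 13 lists ran from 9.81e-12 to 0.619.

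Altogether 6660 of 10377 genes tested changed in microglia, 3361 up and 3299 down, at 2138026 to 13395988 UMIs per library. The groups did not overlap in 7222 (69.6%), where chance gives 10%. The lowest fold changes belonged to genes of other cells. Tagln fell from 467 ± 62.9 to 1.88 ± 0.547 CPM (log2 fold change -7.98 ± 0.18, adjusted p = 6.41e-09, 2.27e-270 to 0.00192 over its alternatives) and stood at 0.711% of its smooth muscle level. Of the pericyte and smooth muscle list, 12 of 13 members fell (camera adjusted p = 7.06e-06, adjusted p = 0.441 with an estimated correlation). All 10 genes named for the largest decreases stood under 5% of their level in another class, 8 of them highest in smooth muscle or pericytes. Called members of the pericyte list stood in sham at a median of 3.06% of the whole library's level, so subtraction of 10% removes more than their counts and does not test them. Igf2 (-6.97 ± 1.77, adjusted p = 0.0254, 5.83e-08 to 0.0977 over its alternatives) was also not called without sham 1 or infarction 1, 2 or 3 (adjusted p = 0.0521, 0.0977, 0.0891 and 0.0779), and could not be tested after subtraction or with genes under 5% of their highest class left out. Of the 10 named for the largest increases, Cd8a (8.65 ± 1.39, adjusted p = 0.00482, 2.39e-16 to 0.0912 over its alternatives) was not called without sham 3 (adjusted p = 0.0721).

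In macrophage-like cells, the comparison set a perivascular cluster, which held most of the class in sham, against the clusters led by Apoc1 and Mx1, which held most of it in infarction. Spp1 rose from 12.7 ± 7.34 to 30263 ± 8969.6 CPM (log2 fold change 11.24 ± 0.50, adjusted p = 2.41e-05). Fn1, encoding the matrix protein fibronectin, had 2 UMIs in sham and rose to 1658 ± 343 CPM, a ratio of 497 to 14819 (95% counting interval, adjusted p = 7.00e-08). Arg1 had 0 UMIs in sham and was at least 275-fold higher (adjusted p = 0.000901, 2.12e-18 to 0.0346 over its alternatives). Slpi, a protease inhibitor gene most abundant in neutrophils here, was at least 1371-fold higher (adjusted p = 0.0126, 8.61e-21 to 0.0580 over its alternatives), but not called without infarction 3 (adjusted p = 0.0580). The complement genes C1qa (log2 fold change -4.25 ± 0.14, adjusted p = 4.16e-08, 2.19e-173 to 0.196 over its alternatives) and C3 (-5.10 ± 0.19, adjusted p = 1.08e-07) fell, as did Csf1r (-2.28 ± 0.10, adjusted p = 1.82e-07) and the class II gene RT1-Ba (-2.31 ± 0.18, adjusted p = 1.04e-05). Spp1, Gpnmb and Lgals3 are also among the leading genes of the cluster that held most infarction cells of this class, so their level here follows the clustering in part.

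Homeostatic microglia genes fell in macrophage-like cells (12 of 15 fell, 12 adjusted over the list alone, camera adjusted p = 1.33e-06, adjusted p = 0.441 with an estimated correlation). MHC class II genes (8 of 10 fell, 9 adjusted over the list alone, camera adjusted p = 0.000912) fell as well. MHC class I genes (1 of 13 rose and 9 fell, 1 up and 9 down adjusted over the list alone, camera adjusted p = 0.01) fell too. Complement genes did likewise (2 of 15 rose and 10 fell, 2 up and 10 down adjusted over the list alone, camera adjusted p = 0.01). Cholesterol biosynthesis genes fell (1 of 22 rose and 12 fell, 1 up and 12 down adjusted over the list alone, camera adjusted p = 0.01), with Srebf2 at -2.08 ± 0.15. Hypoxia and glycolysis genes rose (20 of 21 rose, 20 up and 1 down adjusted over the list alone, camera adjusted p = 1.06e-06, adjusted p = 0.469 with an estimated correlation). In that list Ldha changed by 3.63 ± 0.16 and Gapdh by 3.37 ± 0.17. Respiratory chain genes such as Cox5a (1.82 ± 0.12) rose too (24 of 27 rose, 24 adjusted over the list alone, camera adjusted p = 3.29e-06). Genes of the unfolded protein response such as Manf (2.06 ± 0.16) rose (12 of 16 rose, 12 adjusted over the list alone, camera adjusted p = 0.000412). Antioxidant genes such as Prdx1 (2.85 ± 0.13) rose (10 of 16 rose, 11 adjusted over the list alone, camera adjusted p = 0.00133). Lipid efflux and droplet genes rose (12 of 17 rose and 1 fell, 12 up and 1 down adjusted over the list alone, camera adjusted p = 0.00304), the droplet coat gene Plin2 by 3.37 ± 0.19. Disease-associated microglia genes rose (15 of 21 rose and 4 fell, 15 up and 4 down adjusted over the list alone, camera adjusted p = 0.0108), the protease gene Ctsd by 4.34 ± 0.26. With an estimated correlation the adjusted p of the 12 called lists was 0.441 to 0.619, and over all alternatives 4.27e-07 to 0.619.

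Within the perivascular cluster alone, a subset chosen after seeing the data, 1173 genes changed, 656 up and 517 down, and 1026 of them were also called in the whole class. For the genes of this class named above the changes were smaller there, and Fn1 and Arg1 had too few counts to be tested. Csf1r changed by -0.74, adjusted p = 0.00131, C3 by -2.21, adjusted p = 5.62e-07 and RT1-Ba by -0.65, adjusted p = 0.00763. Ldha changed by 1.54, adjusted p = 7.43e-05, Prdx1 by 1.51, adjusted p = 7.60e-06 and Spp1 by 6.97, adjusted p = 0.00229. C1qa went the other way (0.22, adjusted p = 0.196), as did C1qb (0.57, adjusted p = 0.00698). In that cluster 4 of 12 homeostatic genes, 2 of 6 class II genes, 3 of 12 class I genes and 2 of 17 cholesterol genes fell. Complement genes rose in 1 and fell in 3 of 14, lipid efflux genes rose in 2 and fell in 2 of 13, and disease-associated microglia genes rose in 7 and fell in 2 of 20. Antioxidant genes rose in 4 of 12, and 0 of 7 pericyte genes were called. Hypoxia and glycolysis genes rose in 9 and fell in 1 of 16, unfolded protein response genes rose in 9 of 12, respiratory chain genes rose in 7 and fell in 1 of 27, and cytokines and chemokines rose in 10 and fell in 1 of 17.

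Over the whole class 5787 of 10477 genes tested changed, 3111 up and 2676 down, at 744423 to 35262934 UMIs per library. The groups did not overlap in 6765 (64.6%), where chance gives 10%. With sums thinned to the shallowest library 3115 genes were called, 2821 of them shared, and with automatic doublet thresholds, where the Apoc1 cluster is left out, 3471. Most calls were then decreases, as with DESeq2 and without infarction 3. Tagln fell from 1577 ± 1305 to 2.24 ± 2.28 CPM (log2 fold change -9.37 ± 1.28, adjusted p = 0.00367, 3.39e-20 to 0.177 over its alternatives), and the pericyte and smooth muscle list fell in 12 of 12 members (camera adjusted p = 6.44e-06, adjusted p = 0.502 with an estimated correlation). All 12 stood under 5% of their level in smooth muscle or pericytes, and in sham at a median of 7.55% of the whole library's level. Extracellular matrix genes were not called (adjusted p = 0.251). The interferon list was not called in macrophages (2 of 26 rose and 6 fell, 2 up and 5 down adjusted over the list alone, camera adjusted p = 0.305). Neither was the cytokine list (6 of 23 rose and 5 fell, 6 up and 5 down adjusted over the list alone, camera adjusted p = 0.335). The NF-kappa-B list was not called either (7 of 16 rose and 2 fell, 7 up and 3 down adjusted over the list alone, camera adjusted p = 0.305).

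In oligodendrocyte-like cells, which here join precursors and mature cells, Gal and members of the reactive astrocyte list rose. With automatic doublet thresholds the 2 kinds form separate clusters, and precursors made up 60.9% ± 28.5 of both in sham and 41.9% ± 30.2 in infarction (exact permutation p = 0.5). Gal (ENSRNOG00000015156), encoding galanin, had 0 UMIs in sham and 2082 ± 1083 CPM in infarction, at least 1861-fold higher (adjusted p = 0.00803, 1.91e-22 to 0.0411 over its alternatives). Gal was not tested in the mature cells under those thresholds, but in precursors alone it rose from 0 UMIs in 204 sham cells (adjusted p = 1.53e-12) and was found in 61.5%, 70.5% and 27.6% of infarction precursors. It is also among the 10 leading genes of the class's cluster and of the precursor cluster, as is Olig1. Of the oligodendrocyte-like cells, 33 of 68, 38 of 155 and 25 of 274 held a Gal UMI in infarction 1, 2 and 3 (48.5%, 24.5% and 9.12%), at median depths of 4758, 1400 and 1369.5 UMIs. In sham the counts were 0 of 105, 0 of 84 and 0 of 208, which allow up to 2.86%, 3.57% and 1.44% of cells with a UMI, at median depths of 6171, 6759.5 and 4731. T or NK-like cells of the same infarction libraries, which should lack the gene, held 1 of 67, 0 of 120 and 1 of 96, at median depths of 5666, 5075 and 5031.5. Timp1, an inhibitor of matrix proteases, rose from 5.32 ± 1.46 to 474 ± 49.4 CPM (log2 fold change 6.54 ± 0.33, adjusted p = 0.000350), and S100a10, which binds annexins, rose from 22.5 ± 10.5 to 2322 ± 1123 CPM (log2 fold change 6.64 ± 0.62, adjusted p = 0.00526). Cd44 rose from 1.34 ± 1.51 to 257 ± 151 CPM (log2 fold change 7.60 ± 0.79, adjusted p = 0.00702, 1.34e-14 to 0.0369 over its alternatives). Tnfrsf12a, a cytokine receptor gene induced by injury, rose by 4.37 ± 0.37, adjusted p = 0.00297, 2.70e-16 to 0.0265 over its alternatives. Emp1, with 2 UMIs in sham, rose by a ratio of 31.6 to 962 (adjusted p = 0.00919, 9.86e-08 to 0.0492 over its alternatives).

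Cell cycle genes rose in oligodendrocyte-like cells (16 of 23 rose, 23 adjusted over the list alone, camera adjusted p = 9.03e-13, adjusted p = 0.502 with an estimated correlation), with the mitotic genes Ccnb1 (5.39 ± 0.55, adjusted p = 0.00565, 2.96e-09 to 0.0364 over its alternatives) and Bub1 (4.55 ± 0.52, adjusted p = 0.00803, 1.32e-07 to 0.0425 over its alternatives). The reactive astrocyte list, which holds Timp1, S100a10, Cd44 and Emp1, rose (10 of 13 rose, 11 adjusted over the list alone, camera adjusted p = 2.09e-08, adjusted p = 0.441 with an estimated correlation). The disease-associated oligodendrocyte list was called higher (5 of 12 rose, 7 up and 1 down adjusted over the list alone, camera adjusted p = 0.00614, adjusted p = 0.441 with an estimated correlation). Its member Il33, an alarmin cytokine gene, rose from 117 ± 69.6 to 2893 ± 1790.3 CPM (log2 fold change 4.64 ± 0.80, adjusted p = 0.0184, 1.05e-10 to 0.0880 over its alternatives), but was not called without sham 1 or 2 or infarction 2 (adjusted p = 0.0693, 0.0593 and 0.0663). Oligodendrocyte precursor genes fell (7 of 14 fell, 12 adjusted over the list alone, camera adjusted p = 2.25e-06, adjusted p = 0.502 with an estimated correlation). Of these Olig1, a lineage transcription factor, fell from 1952 ± 769 to 521 ± 105 CPM (log2 fold change -1.91 ± 0.38, adjusted p = 0.0225, 1.05e-08 to 0.847 over its alternatives), and was not called without sham 1 or 2 or infarction 1 or 2 (adjusted p = 0.0817, 0.0685, 0.0558 and 0.111). In precursors alone, a subset chosen after seeing the data, Olig1 fell by 2.67 (adjusted p = 1.05e-08) with 14 of 14 tested genes of the precursor list. There 22 of 23 proliferation genes and 8 of 11 reactive astrocyte genes rose, and 6 of 10 myelin genes fell and 1 rose.

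The myelin list was called lower (3 of 21 fell, 3 adjusted over the list alone, camera adjusted p = 0.000468). The oligodendrocyte differentiation list was called lower (1 of 13 fell, 2 adjusted over the list alone, camera adjusted p = 0.00271), as was the cholesterol biosynthesis list (1 of 20 fell, 0 adjusted over the list alone, camera adjusted p = 0.000627), and few members of the 3 lists passed on their own. The median log2 fold changes were -1.35, -0.84 and -1.09. Cytokines and chemokines (7 of 11 rose, 8 adjusted over the list alone, camera adjusted p = 3.21e-06) were higher. Disease-associated microglia genes (10 of 17 rose, 11 adjusted over the list alone, camera adjusted p = 2.35e-05) and complement genes (4 of 6 rose, 5 adjusted over the list alone, camera adjusted p = 0.00581) were higher. Several of their members stood far below another class, for example Lgals3 (6.62 ± 0.67) at 4.57% of its macrophage level. After subtraction of free RNA the microglia list had an adjusted p of 0.587 and the complement list could not be tested. The lists of p53 and apoptosis (5 of 12 rose, 8 adjusted over the list alone, camera adjusted p = 6.81e-05) and MHC class I presentation (3 of 11 rose, 6 adjusted over the list alone, camera adjusted p = 0.00179) were called higher. So were those of hypoxia and glycolysis (2 of 18 rose, 5 adjusted over the list alone, camera adjusted p = 0.00410) and heat shock (3 of 13 rose, 6 adjusted over the list alone, camera adjusted p = 0.00614). With an estimated correlation the adjusted p of the 18 called lists was 0.441 to 0.632, and fry did not call 8 of them.

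The remaining oligodendrocyte lists leaned on single libraries. The list of immediate early genes, which are also induced by tissue dissociation, was called higher (6 of 14 rose, 6 adjusted over the list alone, camera adjusted p = 0.00828), but not without sham 3 (adjusted p = 0.0988). The unfolded protein response list was called higher (3 of 13 rose, 3 adjusted over the list alone, camera adjusted p = 0.0135), but not without infarction 1 (adjusted p = 0.0682). The antioxidant list was called higher (3 of 13 rose, 5 adjusted over the list alone, camera adjusted p = 0.0461), but not without sham 1 (adjusted p = 0.119) or infarction 1 (adjusted p = 0.0979) or after subtraction of free RNA (adjusted p = 0.106). Subtraction also ended the call of the disease-associated oligodendrocyte list (adjusted p = 0.0511). The pericyte and smooth muscle list fell (8 of 10 fell, 9 adjusted over the list alone, camera adjusted p = 2.39e-09), with Acta2 at 1.03% of its smooth muscle level, and in sham at 3.51% of the whole library's level. Over all alternatives the adjusted p of the 18 lists ran from 3.70e-23 to 0.632.

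In all, 1011 of 8012 genes tested changed in oligodendrocyte-like cells, 637 up and 374 down, at 632547 to 1904115 UMIs per library. The groups did not overlap in 2847 (35.5%), where chance gives 10%. The count depended on single libraries. With 1 left out it was 51 (sham 1), 80 (infarction 2), 297 (sham 2), 439 (infarction 1), 637 (sham 3) and 1352 (infarction 3), and without sham 3 most calls were decreases (270 up and 367 down). With automatic doublet thresholds 55 genes were called in the mature cells, with as few as 16 cells per library. Precursors alone gave 2828 of 6111. After subtraction of free RNA 626 were called. Among the largest increases of named genes, the transcription factor gene Fosl1 was at least 31.1-fold higher (adjusted p = 0.00950, 2.15e-06 to 0.0508 over its alternatives) but not called without infarction 2 (adjusted p = 0.0508). The neuropeptide gene Calcb was at least 65.8-fold higher (adjusted p = 0.0238, 6.21e-08 to 0.0935 over its alternatives) but not called without sham 1, 2 or 3 or infarction 2 (adjusted p = 0.0725, 0.0547, 0.0521 and 0.0729). Tac3, a tachykinin gene, was at least 19.1-fold lower (adjusted p = 0.0144, 8.04e-05 to 0.0618 over its alternatives) but not called without sham 1 or infarction 2 (adjusted p = 0.0618 and 0.0505).

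In T or NK-like cells Foxp3, Tnfrsf4 and Cks2 rose, and Hspa1a and Dnajb1 fell. Foxp3 (ENSRNOG00000011702), the transcription factor of regulatory T cells, rose from 3.98 ± 3.45 to 44.6 ± 24.5 CPM (log2 fold change 3.29 ± 0.60, adjusted p = 0.00451, 4.05e-10 to 0.0395 over its alternatives). Tnfrsf4, a costimulatory receptor gene, rose from 3.02 ± 4.23 to 60.7 ± 29.7 CPM (log2 fold change 4.31 ± 0.73, adjusted p = 0.00668, 8.77e-17 to 0.0552 over its alternatives), but was not called without sham 2 (adjusted p = 0.0552). Cks2, a cell cycle gene, rose from 18.6 ± 10.0 to 227 ± 36.2 CPM (log2 fold change 3.53 ± 0.29, adjusted p = 7.30e-07). The hypoxia-inducible factor gene Hif1a changed by 1.74 ± 0.24, adjusted p = 0.000150. The inducible chaperone gene Hspa1a fell from 733 ± 261 to 91.1 ± 31.9 CPM (log2 fold change -3.00 ± 0.35, adjusted p = 0.00353), and its partner Dnajb1 fell from 367 ± 29.8 to 123 ± 24.1 CPM (log2 fold change -1.58 ± 0.17, adjusted p = 6.34e-06).

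The NF-kappa-B feedback list was called higher in these cells (4 of 10 rose, 7 adjusted over the list alone, camera adjusted p = 1.43e-05, adjusted p = 0.486 with an estimated correlation). Among them Nfkbia, the inhibitor of the pathway, changed by 1.07 ± 0.18, adjusted p = 0.00104 and Nfkbiz by 1.51 ± 0.29, adjusted p = 0.00282. The heat shock list was called lower (4 of 12 fell, 5 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.466 with an estimated correlation). The proliferation list was called higher (2 of 10 rose, 5 adjusted over the list alone, camera adjusted p = 0.000203), as was the hypoxia and glycolysis list (2 of 11 rose, 3 adjusted over the list alone, camera adjusted p = 0.00571), the latter not after subtraction of free RNA (adjusted p = 0.274). With an estimated correlation the adjusted p of the 8 called lists was 0.371 to 0.672. The type I interferon list was called higher (2 of 14 rose, 3 adjusted over the list alone, camera adjusted p = 0.0396) but not without sham 1, 2 or 3 or infarction 1 or 3 (adjusted p = 0.0508, 0.220, 0.0603, 0.281 and 0.241). The blood-brain barrier list, of which the transferrin receptor gene Tfrc had an adjusted p of 0.0394 (1.38; 0.0248 to 0.460 over its alternatives) and was not called without any 1 of the 6 libraries (0.0600 to 0.147), with DESeq2, with a replicate block, with no filter or after subtraction, was called higher (1 of 6 rose, 2 adjusted over the list alone, camera adjusted p = 0.0176) but not without infarction 3 (adjusted p = 0.0501). The disease-associated microglia list was called higher (3 of 12 rose, 5 up and 1 down adjusted over the list alone, camera adjusted p = 0.000315), but not without sham 1 (adjusted p = 0.0571). Of these 12 genes, 9 stood under 5% of another class (Spp1 at 1.03% of macrophages), and after subtraction the list was called lower (adjusted p = 0.0361).

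The pericyte and smooth muscle list fell in 8 of 8 members (camera adjusted p = 1.01e-19, adjusted p = 0.371 with an estimated correlation), with a median log2 fold change of -7.00, or -5.76 with 3 genes at their bound. Tagln fell from 440.0 ± 65.3 to 2.87 ± 2.71 CPM (log2 fold change -7.34 ± 0.35, adjusted p = 5.59e-10, 2.54e-109 to 0.0297 over its alternatives) and stood at 0.696% of its smooth muscle level, and the called members stood in sham at a median of 2.83% of the whole library's level. In this class 339 of 4637 genes tested changed, 212 up and 127 down, at 373396 to 885486 UMIs per library. The groups did not overlap in 1193 (25.7%), where chance gives 10%. Without infarction 2 the count was 201. Over all alternatives the adjusted p of the 8 lists ran from 4.62e-20 to 0.672.

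In endothelial-like cells 2 metallothionein genes rose, and the unfolded protein response list was called higher (adjusted p = 0.466 with an estimated correlation). Mt1 rose from 422 ± 54.7 to 1397 ± 206 CPM (log2 fold change 1.73 ± 0.16, adjusted p = 1.26e-05, 2.35e-19 to 0.178 over its alternatives) and Mt2A by 3.74 ± 0.38, adjusted p = 0.000727, 3.65e-51 to 0.102 over its alternatives. Neither was called with at most 10% mitochondrial UMIs (adjusted p = 0.178 and 0.102), where as few as 6 cells per library were left. Hspa5, the main chaperone of the endoplasmic reticulum, rose from 272 ± 46.1 to 826 ± 282 CPM (log2 fold change 1.60 ± 0.23, adjusted p = 0.000915), and Hsp90aa1 by 1.15 ± 0.18, adjusted p = 0.000638. Adamts4 (ENSRNOG00000003538), a protease that cleaves matrix proteoglycans, had 2 UMIs in sham and rose by a ratio of 16.6 to 562 (adjusted p = 0.000115, 2.05e-12 to 0.00508 over its alternatives). Tgfb2, a growth factor gene, fell from 157 ± 49.6 to 8.18 ± 4.15 CPM (log2 fold change -4.09 ± 0.42, adjusted p = 4.15e-05), and Sbspon fell by 4.36 ± 0.52 on the log2 scale (adjusted p = 0.000653). The Wnt modulator gene Dkk2 was at least 17.4-fold lower (adjusted p = 0.000107, 8.01e-18 to 0.0541 over its alternatives), and Cyp26b1, which breaks down retinoic acid, was lower by a ratio of 11.2 to 339 (95% counting interval, adjusted p = 3.72e-05).

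The unfolded protein response rose in endothelial-like cells (7 of 12 rose, 10 adjusted over the list alone, camera adjusted p = 1.35e-06, adjusted p = 0.466 with an estimated correlation). Members were Calr at 1.09 ± 0.18 and Hsp90b1 at 0.90 ± 0.19. The hypoxia and glycolysis list was called higher (7 of 16 rose, 9 up and 1 down adjusted over the list alone, camera adjusted p = 0.000204), with Hif1a (1.31 ± 0.22) and Pgk1 (1.30 ± 0.20). The antioxidant list was called higher (6 of 14 rose, 8 up and 2 down adjusted over the list alone, camera adjusted p = 0.00201), with the superoxide dismutase gene Sod2 (2.46 ± 0.24). The iron and haem list (3 of 8 rose, 6 adjusted over the list alone, camera adjusted p = 5.07e-05) and the heat shock list (4 of 12 rose, 6 adjusted over the list alone, camera adjusted p = 0.00570) were called higher, the latter not without infarction 1 (adjusted p = 0.198). So were the lists of disease-associated microglia (7 of 15 rose, 10 adjusted over the list alone, camera adjusted p = 6.37e-09) and cytokines and chemokines (2 of 13 rose, 6 adjusted over the list alone, camera adjusted p = 7.06e-06). The lists of lysosome (3 of 18 rose, 3 adjusted over the list alone, camera adjusted p = 0.000284), lipid efflux (3 of 11 rose, 5 up and 1 down adjusted over the list alone, camera adjusted p = 0.00432) and NF-kappa-B feedback genes (2 of 9 rose, 3 up and 1 down adjusted over the list alone, camera adjusted p = 0.0284) were also called higher. After subtraction of free RNA the adjusted p values of these 5 lists were, in that order, 0.135, 0.175, 0.195, 0.0615 and 0.0796. Their members included Ccl2 at 1.96% of neutrophils and Spp1 at 6.76% of macrophages. With an estimated correlation the adjusted p of the 10 called lists was 0.441 to 0.553, and over all alternatives 8.30e-12 to 0.553.

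Blood-brain barrier genes (1 of 16 fell, 2 up and 1 down adjusted over the list alone, camera adjusted p = 0.530) and genes of endothelial activation and sprouting (2 of 17 rose and 2 fell, 3 up and 2 down adjusted over the list alone, camera adjusted p = 0.238) were not called in endothelial-like cells. In total 599 of 6046 genes tested changed, 271 up and 328 down, at 247600 to 2163328 UMIs per library. The groups did not overlap in 1885 (31.2%), where chance gives 10%. The count was 373 without infarction 1 and 350 without infarction 2. It was 370 with at most 10% mitochondrial UMIs, 1277 with no filter on low counts and 1042 with automatic doublet thresholds. Most calls were increases with DESeq2, without infarction 3, with doublets kept and with automatic doublet thresholds.

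The infarction effect was compared between microglia-like and macrophage-like cells of the same libraries, the 2 tested classes with the most cells. Of 9823 genes tested in both, 4101 changed in both, and 3704 of these in the same direction. Of these, 2032 rose in both and 1672 fell in both, and as both classes come from the same 6 libraries no chance value is given. The cyclin gene Ccnd1 differed between the classes by 4.26 ± 0.12, falling in macrophages (-3.25) and rising in microglia (1.04). The chemokine gene Cxcl16 (-1.92 and 1.71) and the cell cycle inhibitor gene Cdkn2c (-3.10 and 2.14) did likewise. The lysosomal genes Lamp1 (0.98 and -1.10), Psap (0.66 and -1.15) and Rnaset2 (0.98 and -1.20) went the other way. The test of the difference called 3886 of 11246 genes, 1812 with the higher change in microglia and 2074 in macrophages. That majority turned with DESeq2 and its size factors. Of these 3886 genes 396 were called in both classes in opposite directions. With perivascular macrophages alone 1078 genes differed, 748 of them shared, and the Ccnd1 difference was 1.19. With macrophages of every cluster drawn once at random to the number of those cells and thinned to their depth, also chosen after seeing the data, 2015 genes differed (1211 and 804) and the Ccnd1 difference was 4.32.

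Over all classes, camera called 81 of 185 list and class pairs, 58 higher and 23 lower, with 91 at an unadjusted p under 0.05, but another split of the 6 libraries also called 81. With an estimated correlation camera called 0, with 17 at an unadjusted p under 0.05 and a lowest adjusted p of 0.371, while fry called 102, 70 of them shared. The median and the mean of the members had the sign of the test in all 81. Genes of axon growth and regeneration (lowest adjusted p = 0.163), neurotrophic and growth factors (0.393), synapse and neuronal signalling (0.296) and endothelial activation and sprouting (0.238) were called in 0 of the classes where they were tested.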

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

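The tests with perivascular macrophages alone and with macrophages drawn to their number and depth were chosen only after the result was seen. The infarction effect differed between macrophage-like and microglia-like cells in 3886 genes, by an edgeR test of the interaction of class and group. This difference between 2 classes is why the result deserves a second look. The genes with the smallest p included Plxnd1, a semaphorin receptor gene, which changed by -2.25 in macrophages and 3.31 in microglia, and Lhfpl2, which changed by 3.98 and -1.06. For Vcam1, an adhesion molecule gene, the change was -5.94 in macrophages and -0.18, not called, in microglia.

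With perivascular macrophages alone the differences for Plxnd1, Lhfpl2 and Vcam1 were 4.54, -1.88 and 1.76, and 1078 genes differed, 748 of them shared with the whole class. Macrophages of every cluster, drawn once to the number and depth of the perivascular cells, gave 2015 genes and differences of 6.63, -5.07 and 9.77, so lower depth and fewer cells reduce the count by themselves. At that same depth the perivascular cells gave fewer genes. Among the 10 splits of the 6 libraries, 1 gave as many genes, the real one, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.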

How the results depend on the processing

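Tests under automatic doublet thresholds, free RNA subtraction, perivascular macrophages alone, macrophages drawn to their number and depth, microglia without the cycling cluster, oligodendrocyte precursors alone, and shares without smooth muscle, pericyte and choroid plexus cells were chosen only after the results were seen. Of 3947 values of 411 named genes under alternatives other than leaving out a library, 3715 kept direction and call, 143 lost the call, 83 gained it and 6 reversed. Of 2456 values with 1 library left out, 2139 kept both, 293 lost the call, 24 gained it and 0 reversed. For 185 list and class pairs the 686 alternative values split into 537, 104, 40 and 5, and the 1098 without a library into 1036, 19, 43 and 0. Some alternatives left few cells, as few as 6 endothelial cells and 16 oligodendrocytes per library.

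Genes called without 1 library ranged from 4148 to 5382 in macrophages, 5909 to 6555 in microglia, 51 to 1352 in oligodendrocytes, 201 to 343 in T or NK cells, 350 to 580 in endothelial cells and 9342 to 10561 over all cells. Lists ranged from 81 to 89, the class difference from 3213 to 3468 genes and abundance from 8 to 10 classes. Shares (infarction minus sham, percentage points) ranged from -0.666 to -0.139 for T or NK, -5.04 to -2.31 for astrocytes, -4.58 to -1.67 for choroid plexus, -1.51 to -0.230 for endothelial, -0.15 to 0.191 for ependymal, -2.53 to -1.52 for fibroblasts, 22.6 to 29.5 for macrophages, -9.86 to 0.177 for microglia, -1.37 to -0.418 for neurons, 17.5 to 26.8 for neutrophils, -0.447 to 1.28 for oligodendrocytes, -26.8 to -21.9 for pericytes, -38.1 to -33.0 for smooth muscle and 24.2 to 28.0 for unnamed cells.

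Counts moved by over 1.5 times as follows, and where no reason is given the cause was not tested. With no filter on low counts, T or NK cells gave 577 genes and endothelial cells 1277, from more genes tested. DESeq2 gave 218 in T or NK cells. With at most 10% mitochondrial UMIs endothelial cells gave 370, from fewer cells. Automatic doublet thresholds gave 1042 in endothelial cells, 3471 in macrophages, whose largest infarction cluster stayed unnamed, and 55 in oligodendrocytes, whose precursors split off and alone gave 2828. Thinned sums gave 3115 in macrophages, free RNA subtraction 626 in oligodendrocytes, and perivascular macrophages alone 1173 genes and 1078 in the class difference. Macrophages drawn to their number and depth gave 2982 genes and 2015 in the class difference, so fewer cells and lower depth together account for part of the fall. Lists with an estimated correlation came to 0. The direction of most calls (up and down) turned in endothelial cells with DESeq2 (330 and 244), without infarction 3 (333 and 247), with doublets kept (464 and 428) and with automatic doublet thresholds (542 and 500). It turned in macrophages with DESeq2 (2923 and 3180), thinned sums (1547 and 1568), automatic doublet thresholds (1713 and 1758), the drawn cells (1446 and 1536) and without infarction 3 (2172 and 2225), in microglia with doublets kept (3507 and 3571), and in oligodendrocytes without sham 3 (270 and 367) and in precursors alone (1413 and 1415). In the class difference it turned with DESeq2 (1878 and 1560), its size factors (1981 and 1815), perivascular macrophages (571 and 507) and the drawn cells (1211 and 804).

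Shares reversed for ependymal cells with at most 10% mitochondrial UMIs (-0.379), without mural and choroid cells (-0.831), and without infarction 2 (-0.15), sham 1 (-0.132) or sham 2 (-0.0539). They reversed for microglia at resolution 0.5 (1.15) and without sham 3 (0.177), and for oligodendrocytes with at most 10% mitochondrial UMIs (-0.949), without mural and choroid cells (-3.22) and without infarction 3 (-0.447). The ependymal abundance was -2.11 with at most 10% mitochondrial UMIs. Free RNA subtraction reversed the extracellular matrix list in macrophages (adjusted p = 0.00540), disease-associated microglia (0.0361) and lysosome (0.000596) lists in T or NK cells, and the pericyte list in endothelial cells (1.59e-07). Fry reversed heat shock over all cells (0.00922). Tagln in microglia gave 6.69 after subtraction, which exceeds its sham level. C1qa and C1qb in perivascular macrophages gave 0.22 and 0.57, Olig1 and Pllp in oligodendrocytes with automatic doublet thresholds, so in mature cells alone, 0.18 and 0.00290, and Tf in endothelial cells with at most 10% mitochondrial UMIs -1.09. Other causes were not tested.

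The labels give replicates of both groups the same numbers without saying that they are paired. Correlations of same-numbered deviations were 0.0277, 0.0641 and -0.0489 in macrophages, 0.0642, 0.105 and 0.0105 in microglia, 0.151, -0.0981 and 0.455 in oligodendrocytes, -0.0329, -0.0282 and -0.0513 in T or NK cells, -0.0475, 0.0255 and -0.108 in endothelial cells and 0.0184, -0.0592 and 0.109 over all cells. At most 2 of 3 sham samples best matched their own number. With the number as a block 5431, 6563, 1451, 338, 578 and 9728 genes were called in that order, 83 lists and 9 abundance classes.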

Other observations

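Apart from the counts over other splits of the samples and the test of the filters, the tests below, with their limits, were chosen only after the results were seen. In the infarction libraries, signalling transcripts came from different cells (share of a gene's UMIs, mean ± SD, n = 3). Among chemokines, microglia-like cells held 80.2% ± 2.16 of Ccl4 UMIs, T or NK-like cells 92.8% ± 3.12 of Ccl5, and macrophage-like cells 73.8% ± 8.01 of Ccl12 and 71.1% ± 8.64 of Ccl7. For Ccl2 the macrophage-like cells held 45.4% ± 13.7, the unnamed cluster led by Fcnb and Vcan 29.8% ± 4.67 and neutrophil-like cells 18.7% ± 10.2. Neutrophil-like cells held 46.7% ± 8.33 of Ccl3 UMIs and 38.9% ± 6.17 of Cxcl2. For interleukin genes, neutrophil-like cells held 44.1% ± 3.47 of Il1b and 38.5% ± 4.19 of its antagonist Il1rn, against 22.0% ± 0.892 of Il1b in microglia-like cells.

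Growth factor and alarmin transcripts had these sources. Oligodendrocyte-like cells held 59.1% ± 8.22 of Il33 UMIs and microglia-like cells 30.9% ± 8.12. Macrophage-like cells held 56.3% ± 6.19 of Igf1 UMIs and microglia-like cells 35.0% ± 7.10. Macrophage-like cells also held 67.3% ± 11.4 of Gdf15, 40.5% ± 10.7 of Osm, 42.0% ± 9.75 of Pdgfa, 39.8% ± 6.74 of Tgfb1 and 39.5% ± 8.63 of Vegfa. A share reflects both the level in a cell and the number of cells kept.

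Few smooth muscle and pericyte-like cells were found in infarction. Removal by the filters is argued against, since over all deposited barcodes at most 3 in an infarction library had at least 1% smooth muscle UMIs, against 3855 to 4301 in sham. Placement in another class is too, since the smooth muscle markers took 0.0282% of their sham share of UMIs over all deposited barcodes. A loss of vessels of every cell type would keep mural cells per endothelial cell in the sham range, but the highest infarction value was 0.12 and the lowest sham value 16.9. Tissue handling that differed between groups cannot be told apart from the infarct, since choroid plexus cells, at the edge of the tissue, also went from at least 17 per sham library to at most 2, and injury to mural cells may play a part as well.

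Free RNA may account for the lower smooth muscle genes in microglia, macrophage, oligodendrocyte and T or NK-like cells, as may mural cells caught in the same droplets. In sham, 38 of 40 called members stood within 2-fold of their class's median share of the whole library's level, as 1 source would give, and the others were Tpm1 and Cspg4 in oligodendrocyte-like cells. Among 24 genes highest in infarction that another class holds more of, 18 stood under 200% of the whole library, where free RNA cannot be told apart from expression, and the others, apart from Fosl1, are left open. It is argued against for Gal, Calcb and Fosl1 in oligodendrocyte-like cells (lowest 861%). A changed mix of precursors and mature cells is argued against for Gal. It rose in the precursor cluster alone (log2 13.61 in the model, with sham at 0). Gal leads that cluster and its precursor genes fell, so other cells joining it are left open. A response of these cells to the infarct remains a hypothesis that labelling these genes in undissociated tissue of both groups could decide.

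Homeostatic genes were lower in microglia-like cells. Macrophages counted as microglia are argued against as the whole cause, since 20 abundant macrophage genes stood at a median of 7.0% of their macrophage level (1.99% to 30.3%) where the median fall would need 77.6%. Depth per cell is left open (median 5053 to 5199 UMIs in sham, 9605 to 17811 in infarction). Thinning sums to the shallowest library, where 15 of 16 members stayed lower, does not change it. Without the cycling cluster 16 did, but cell cycle genes rose too, so cycling is left open. So is tissue handling, as 6 of 16 dissociation stress genes rose and 7 fell. A change of state of microglia after the infarct is a hypothesis that labelling Cx3cr1 in undissociated tissue of both groups could test.

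Other splits of the 6 libraries were counted for every model fitted across genes, and 10 splits are too few for a share under 0.05. The real split and the highest other gave 5787 and 0 genes in macrophages, 6660 and 0 in microglia, 1011 and 0 in oligodendrocytes, 339 and 1 in T or NK cells, 599 and 0 in endothelial cells and 10436 and 0 over all cells. The class difference gave 3886 and 0 genes, and abundance 9 and 0 classes. For each of these 1 split, the real one, gave as large a result. For lists 2 splits did, since another split also called 81 list and class pairs.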
